A study of Caenorhabditis elegans with 12 samples.

How the data were processed

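The deposited table holds 24238 genes with raw read counts and FPKM values for the 12 libraries, per the file headers. All columns of the 12 libraries were used. The authors trimmed reads with cutadapt 1.9, checked them with FastQC, aligned them with HISAT2 2.2.1 and assembled and quantified transcripts with StringTie, according to the submitters' processing notes. The labels describe poly(A)-selected, dUTP-stranded libraries from total RNA. The counting tool and its handling of reads that match several genes are not given in the sources used here, nor is the genome build. Of the gene identifiers, 24232 matched the WBcel235 annotation, and 97.0% of starts and 95.9% of ends were equal, so coordinates are given in WBcel235. The table covers 6 chromosomes and holds 0 mitochondrial genes, so mitochondrial transcripts were not analysed here. Protein-coding genes held 95.1% of the counts and ribosomal RNA 1.82%.

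The choices of filter, test, threshold, gene lists and named genes were fixed before the data were examined. The fixed test was limma on log2(FPKM + 1), because only FPKM values were announced. The table also held counts, so the counts were tested with edgeR instead, as had been written for that case, and the limma result is kept as an alternative. Genes with a mean of at least 1 FPKM over the 12 libraries were tested, 11535 in all, and 12703 lay below. The model had the treatment as its only term, TMM scaling, robust dispersions and a two-sided quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 change is its size divided by the square root of F. Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

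Of 43 fixed gene lists, 41 had at least 3 tested members and were tested with camera at a preset correlation of 0.01. The mitochondrial genome list had 0 members in the table and the coelomocyte and glia list 2 tested members. Each list was also tested with an estimated correlation and with fry, and its members were adjusted over the list alone. Named genes were the 10 largest rises and 10 largest falls in log2(FPKM + 1) among named genes past the threshold whose groups did not overlap. To these came up to 4 members with the smallest p of each list that passed or held 3 or more changed genes, and a fixed set that included cua-1, cuc-1, sod-1, mtl-1, mtl-2, ftn-1 and vit-2. The genes lin-42, col-19, fat-6, hrg-4, nhr-23, argk-1, hsp-70, mcm-3, mcm-7, cdk-1, cyb-1, gsp-3, gsp-4, ifa-1 and ifp-1 were added after their values had been seen, as were the gene ontology terms.

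Principal components were taken from log2 CPM of the tested genes. A list's score in a library is the mean of its members' log2 CPM minus that of the 6 DMSO libraries. Length correction used the summed exon length of each gene, known for 97.2% of tested genes, and a loess fit per library. The alternatives changed the filter, the scaling, the pseudocount, the test, the weights and the libraries used, and added a replicate block. Median-ratio scaling was applied to the counts, and the replicate block was put in the edgeR model. Lists were not tested under DESeq2 or the rank-sum test.

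In a simulation with the dispersions of these data, 50 genes each were changed 1.25-fold, 1.5-fold, 2-fold and 4-fold. The model recovered 8%, 64%, 84% and 100% of them. Far fewer genes were changed there than the 4590 called in these data, so the adjustment for multiple tests was stricter. The shares therefore do not measure how many changes of these sizes go unseen here. In that simulation the model called 5 of 11335 unchanged genes, 3.76% of all calls. In a further simulation with a trend of transcript length and no changed gene, 3055 genes were called, and 1 after length correction. The trend was put equally into all 6 TM libraries. In these data the steepest slopes lay in single libraries, -0.194 in TM replicate 5 and -0.156 in DMSO replicate 6. The simulation therefore does not measure how well the correction works here.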

Results

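Poly(A) RNA of whole animals of N2, the Bristol wild-type strain of the nematode Caenorhabditis elegans, was sequenced in 12 libraries. Of these, 6 came from animals given dimethyl sulfoxide (DMSO), the control, and 6 from animals given tetrathiomolybdate (TM), a copper chelator built from molybdenum and sulfur, for 4 days. The labels give no developmental stage, dose or culture, so the p-values measure the spread between these libraries, which may be technical in part. The deposited table holds 24238 genes, with a count and an FPKM value per library. Total counts ran from 61432401 in DMSO replicate 1 to 67068328 in DMSO replicate 6. A comparison of the totals between the groups gave a two-sided exact permutation p = 0.487. Each library counted as 1 replicate, as the labels number them. The 30 pairs of libraries within a group had a chi-square per degree of freedom between 18.2 and 231 against counting noise, which does not show separate cultures. Levels below are mean FPKM ± SD over 6 libraries of a group, and log2 changes are TM over DMSO ± SE from the count model, with adjusted p from edgeR's quasi-likelihood test.

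The groups separated along the first principal component, which held 73% of the variance. DMSO replicate 6 lay between the groups on that component, at -8.20, with the other DMSO libraries from -58.9 to -39.7 and the TM libraries from 38.3 to 54.9. TM replicate 5 stood apart on the second component, which held 10.2% of the variance, at -39.3 against 9.02 to 15.5 in the other TM libraries, and DMSO replicates 6 and 2 lay the same way at -28.9 and -19.3. More genes reached 1 FPKM in TM, 12037 ± 226 against 10828 ± 132 (two-sided exact permutation p = 0.00216, the smallest such a split allows). The 10 most abundant genes of each library held a smaller share of its counts in TM, 7.75% ± 0.637 against 9.51% ± 0.206 (two-sided exact permutation p = 0.00216).

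**Figure D1:**
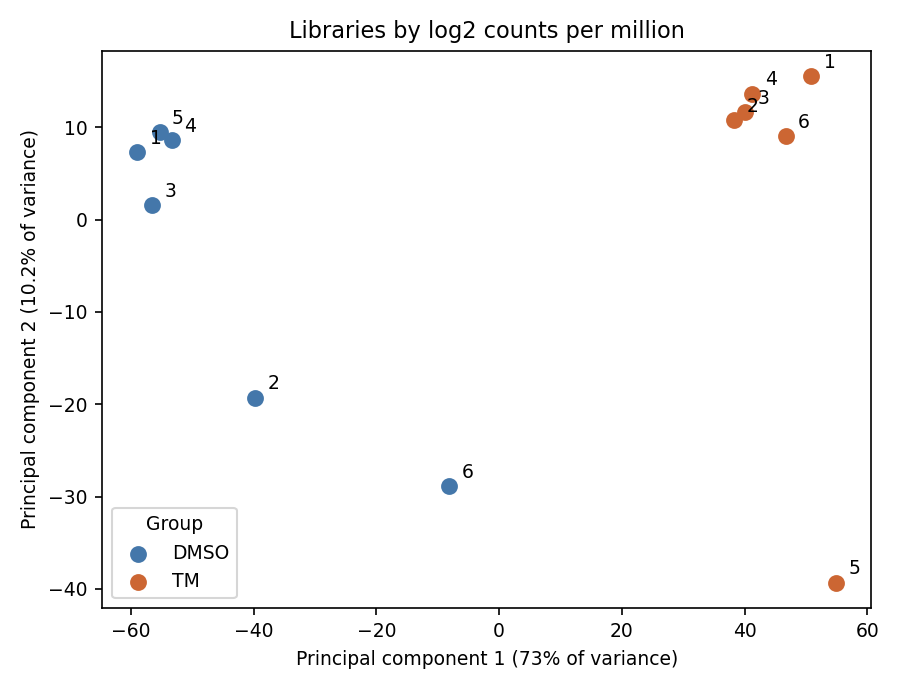
Each point is 1 library, placed by the first and second principal components of log2 CPM over the tested genes, with the replicate number beside it and the share of variance on each axis. DMSO replicate 6 sits at -8.20 on the horizontal axis, between the other DMSO libraries and the TM libraries.

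The comparison of TM with DMSO asks how giving TM changed the transcriptome. Among the gene lists, genes of the cuticle, the collagen coat that a nematode renews at each moult, and genes of sperm rose by the largest amounts. The collagen col-73 (chromosome II, 4872098 to 4873129, minus strand in WBcel235) went from 13.7 ± 15.8 to 182 ± 24.1 FPKM. DMSO replicate 6 had 45.5 FPKM of col-73 and the other DMSO libraries 4.89 to 12.9, and without it the DMSO mean was 7.39 ± 3.17 FPKM and the log2 change 4.6. The sperm gene spe-11 went from 0.445 ± 0.233 to 5.62 ± 1.65 FPKM. The falls were smaller and fewer genes moved far. The lysozyme gene lys-10 (chromosome IV, 8332826 to 8333518, plus strand) went from 71.8 ± 15.2 to 10.3 ± 2.01 FPKM. The gene fat-7 (chromosome V, 7151353 to 7153146, minus strand), which encodes a fatty acid desaturase of the intestine, went from 75.5 ± 14.7 to 17.6 ± 5.05 FPKM. Among copper transport genes the largest change was that of F58G6.9, listed as chca-1 in the reference annotation. This copper transporter gene of the CTR family went from 20.5 ± 2.43 to 42.9 ± 5.28 FPKM.

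Of 11535 genes with a mean of at least 1 FPKM, 4590 (39.8%) passed an adjusted p of 0.05, 2739 of them higher and 1851 lower in TM. A change of at least 1 on the log2 scale was found for 1051 of the risen and 28 of the fallen genes. The median change was 0.75 among risen and -0.29 among fallen genes. In 2593 of the tested genes (22.5%) the 6 TM values lay all above or all below the 6 DMSO values, where chance gives 0.216%. The direction of the balance turned with quantile normalization and in no other setting tried. With median-ratio scaling 54.4% of the calls were higher, and with total counts only 66.9%. In the count model 59.7% of the calls were higher, and limma on log2(FPKM + 1) called 3018 genes higher and 1579 lower, 65.7% higher. The same limma fit after quantile normalization called 1933 higher and 2945 lower, 39.6% higher. Without DMSO replicates 2 and 6 and TM replicate 5, a setting chosen after the libraries had been seen, 6350 genes passed, 3518 higher and 2832 lower.

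Of the 128 tested cuticle collagens, 119 rose and 1 fell (120 and 2 when adjusted over the list alone), with a median log2 change of 3.12. For the collagens, camera gave adjusted p = 1.04e-54, and adjusted p = 0.189 with an estimated correlation. Among genes whose groups did not overlap, the 10 largest rises on the log2(FPKM + 1) scale were all of collagens: col-73 (log2 change 3.66 ± 0.55, adjusted p = 0.000158), dpy-13 (log2 change 3.74 ± 0.52, adjusted p = 7.96e-05), bli-6, dpy-4, dpy-5, col-138, col-133, col-77, col-63 and col-175. The level of dpy-13, needed for normal body shape, went from 9.92 ± 10.8 to 139 ± 21.2 FPKM, with 31.6 FPKM in DMSO replicate 6 and 4.58 to 9.04 in the other DMSO libraries. Without that library the DMSO mean of dpy-13 was 5.58 ± 1.94 FPKM, and the log2 changes of the 10 ran from 4.29 for col-133 through 4.6 for col-73 to 4.62 for dpy-13. Abundant collagens rose too, by smaller factors, such as col-124 from 677 ± 58.6 to 1664 ± 138 FPKM (log2 change 1.26 ± 0.088, adjusted p = 7.24e-07). The adult-stage collagen col-19, chosen after its values were seen, went from 410.2 ± 43.8 to 817 ± 75.9 FPKM (log2 change 0.96 ± 0.095, adjusted p = 4.65e-06). The rises with the smallest p among collagens were those of col-142 (log2 change 1.98 ± 0.13, adjusted p = 7.23e-07), col-124, col-90 and col-92. DMSO replicate 6 carried a higher mean collagen score than the DMSO mean, by 1.17 on the log2 scale, with the other DMSO libraries between -0.42 and 0.20 and the TM libraries between 2.37 and 2.89. The collagen that fell was col-95, and 0 fell without TM replicate 4.

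Genes that act in moulting and in the epidermis moved with the collagens. Of 15 moulting genes 12 rose and 0 fell (12 and 0 adjusted over the list alone), with a median change of 1.004. For the moulting genes, camera gave adjusted p = 9.93e-10, and adjusted p = 0.162 with an estimated correlation. The protease inhibitor gene mlt-11 went from 0.863 ± 0.0880 to 2.70 ± 0.424 FPKM (log2 change 1.61 ± 0.11, adjusted p = 5.89e-07) and mlt-8 from 5.26 ± 1.29 to 23.4 ± 3.08 FPKM (log2 change 2.12 ± 0.16, adjusted p = 1.25e-06). The hedgehog-related gene qua-1 went from 0.828 ± 0.125 to 3.41 ± 0.845 FPKM (log2 change 2.004 ± 0.17, adjusted p = 2.21e-06). Of 13 epidermis and seam markers 8 rose and 2 fell, the same counts when adjusted over the list alone, with a median of 0.91. Of the 13, 3 are collagens counted above. DMSO replicate 6 scored 0.247 for these markers, against -0.0963 to -0.0261 in the other DMSO libraries and 0.725 to 1 in TM. For the moulting genes it scored 0.176, against -0.148 to 0.0546 in the other DMSO libraries and 0.804 to 1.16 in TM. For epidermis and seam markers, camera gave adjusted p = 2.72e-05, and adjusted p = 0.162 with an estimated correlation. The hedgehog-related gene wrt-1 rose (log2 change 2.01 ± 0.15, adjusted p = 1.30e-06), as did the larval collagen dpy-7 (log2 change 1.85 ± 0.15, adjusted p = 1.69e-06). The genes lin-26 and rde-4 were the members that fell, with 1 member falling without DMSO replicate 3 or without TM replicate 2. Of genes chosen after their values were seen, the moulting-cycle gene lin-42 rose from 2.81 ± 0.418 to 8.57 ± 1.66 FPKM (log2 change 1.57 ± 0.15, adjusted p = 2.99e-06). The moulting regulator nhr-23 had 26.5 ± 0.889 FPKM in DMSO and 25.4 ± 1.03 FPKM in TM (log2 change -0.10 ± 0.053, adjusted p = 0.169), and passed with DESeq2 (adjusted p = 0.0444, in a range of alternatives up to 0.631).

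**Figure D2:**
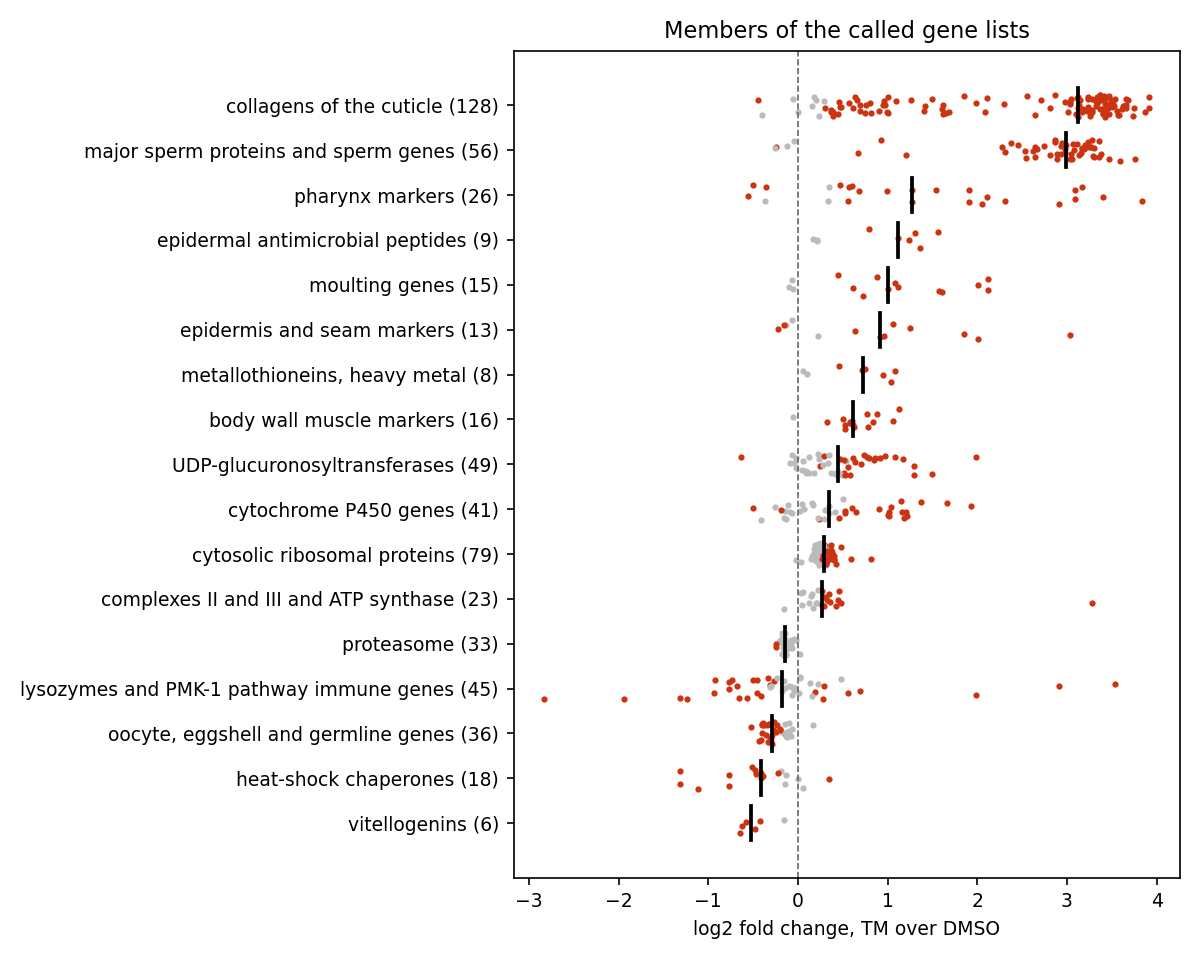
Each row is 1 of the 17 gene lists past the camera threshold, with its number of tested genes in brackets, and each point is a gene, placed by its log2 fold change of TM over DMSO. Red points passed an adjusted p of 0.05, grey points did not, and the black bar is the list's median, 3.12 for the collagens and -0.53 for the vitellogenins.

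Sperm genes rose and genes of oocytes and yolk fell. Of 56 tested major sperm protein and other sperm genes 52 rose and 1, spe-39, fell (52 and 2 adjusted over the list alone), with a median change of 2.99. For the sperm genes, camera gave adjusted p = 4.93e-28, and adjusted p = 0.247 with an estimated correlation. Levels stayed low in DMSO, and spe-11, a sperm-supplied embryonic gene, rose (log2 change 3.59 ± 0.33, adjusted p = 2.80e-06). The sperm-specific gene ssp-35 went from 0.5262 ± 0.332 to 7.65 ± 1.39 FPKM (log2 change 3.76 ± 0.36, adjusted p = 3.61e-06), and smz-1 from 1.07 ± 0.685 to 8.12 ± 1.05 FPKM (log2 change 2.87 ± 0.31, adjusted p = 8.93e-06). The major sperm protein genes are near-identical copies, so how the counting shared reads among them is uncertain for each single gene. The number of sperm genes that fell was 2 without TM replicate 4 or 5, 1 without DMSO replicate 6 or TM replicate 2, and 0 without any other single library. DMSO replicate 6 had a sperm score of 1.46 over the DMSO mean, with the other DMSO libraries between -0.54 and 0.17. Without that library the median change of the sperm genes was 3.60. Of 36 oocyte, eggshell and germline genes 25 fell and 0 rose (27 and 1 adjusted over the list alone), with a median of -0.28. For oocyte and germline genes, camera gave adjusted p = 5.51e-08, and adjusted p = 0.452 with an estimated correlation. The germline gene nos-2 went from 211 ± 4.93 to 150.1 ± 11.8 FPKM (log2 change -0.52 ± 0.068, adjusted p = 4.08e-05). The maternal RNA-binding genes mex-6 (log2 change -0.40 ± 0.061, adjusted p = 0.000141) and pos-1 (log2 change -0.38 ± 0.064, adjusted p = 0.000310) fell as well. So did the egg surface gene egg-1 (log2 change -0.38 ± 0.063, adjusted p = 0.000264). Without DMSO replicate 2, DMSO replicate 6 or TM replicate 1, 1 member of that list rose. Of 6 vitellogenins, the yolk protein genes, 5 fell and 0 rose, the same counts adjusted over the list alone, with a median of -0.53. For the vitellogenins, camera gave adjusted p = 8.50e-05, and adjusted p = 0.417 with an estimated correlation. Their largest fall was that of vit-3, from 1659 ± 107 to 1087 ± 127 FPKM (log2 change -0.64 ± 0.10, adjusted p = 0.000145). The level of vit-2 went from 3439.8 ± 128 to 2613 ± 311 FPKM (log2 change -0.43 ± 0.10, adjusted p = 0.00272). Of 5 tested early zygotic genes 2 fell and 0 rose, the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0928). TM replicate 5 had the lowest score of these, -0.765 against -0.477 to -0.196 in the other TM libraries.

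Muscle and pharynx genes were higher in TM. Of 16 body wall muscle markers 15 rose and 0 fell, the same counts adjusted over the list alone, with a median change of 0.61. For body wall muscle, camera gave adjusted p = 8.04e-10, and adjusted p = 0.221 with an estimated correlation. The troponin genes mup-2 (log2 change 1.06 ± 0.083, adjusted p = 1.42e-06) and tni-1 (log2 change 1.13 ± 0.095, adjusted p = 1.92e-06) rose. So did the myosin heavy chain gene unc-54, from 129 ± 6.47 to 226 ± 23.8 FPKM (log2 change 0.78 ± 0.082, adjusted p = 7.67e-06). Of 26 pharynx markers 20 rose and 3 fell, the same counts adjusted over the list alone, with a median of 1.27. For the pharynx markers, camera gave adjusted p = 1.93e-07, and adjusted p = 0.308 with an estimated correlation. Glutamine- and asparagine-rich abu genes of the pharyngeal cuticle were among those that rose, with abu-14 going from 4.04 ± 1.14 to 15.7 ± 2.36 FPKM (log2 change 1.91 ± 0.18, adjusted p = 3.38e-06) and abu-11 rising too (log2 change 2.11 ± 0.18, adjusted p = 2.23e-06). The genes phat-3, phat-7 and phat-8 were the members that fell. The pharynx score of DMSO replicate 6 was 0.57 over the DMSO mean, against -0.32 to 0.20 in the other DMSO libraries. Neuron markers rose in 8 of 16 and fell in 0 (10 and 0 adjusted over the list alone). Neuropeptides and insulins rose in 19 of 92 and fell in 2 (10 and 1 adjusted over the list alone). Intestine markers rose in 5 of 14 and fell in 2 (the same counts adjusted over the list alone). None of these 3 lists passed, with camera adjusted p of 0.0928, 0.102 and 0.951.

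Lysozymes and fatty acid desaturases held 5 of the 10 largest falls on the log2(FPKM + 1) scale among genes whose groups did not overlap. Lysozymes and PMK-1 pathway immune genes fell in 19 of 45 and rose in 8 (19 and 9 adjusted over the list alone), with a median of -0.17. For lysozymes and immune genes, camera gave adjusted p = 0.000610, and adjusted p = 0.512 with an estimated correlation. The list's call was lost with quantile normalization (adjusted p = 0.0584, the highest of all alternatives, which began at 3.28e-05). Only 5 members rose without DMSO replicate 1 or without DMSO replicate 4. Of the term innate immune response, chosen after its values were seen, 91 of 214 genes rose against 47.5 expected (hypergeometric adjusted p = 3.16e-09). Of these, 69 were in none of the lists, and the hypergeometric test takes genes as independent of each other. The lysozyme genes lys-10 (log2 change -2.83 ± 0.18, adjusted p = 5.89e-07), ilys-2 (log2 change -1.94 ± 0.41, adjusted p = 0.00184) and lys-7 (log2 change -1.23 ± 0.12, adjusted p = 5.35e-06) fell. The gene lys-3 went the other way, from 0.532 ± 0.124 to 6.43 ± 2.29 FPKM (log2 change 3.54 ± 0.26, adjusted p = 1.10e-06). Among 20 genes of fatty acid synthesis 7 fell and 3 rose (7 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0928). The acyl-CoA desaturase genes fat-7 (log2 change -2.13 ± 0.21, adjusted p = 4.75e-06) and fat-5, from 29.8 ± 6.05 to 8.92 ± 3.18 FPKM (log2 change -1.77 ± 0.21, adjusted p = 2.21e-05), fell. The desaturase gene fat-6, chosen after its values were seen, fell less (log2 change -0.36 ± 0.078, adjusted p = 0.00226). The synthase gene fasn-1 rose, from 12.7 ± 1.05 to 17.9 ± 1.11 FPKM (log2 change 0.46 ± 0.057, adjusted p = 2.70e-05). The rest of the 10 largest falls were those of irg-6 (log2 change -1.32 ± 0.21, adjusted p = 0.000225), R11A5.3, ZK822.9, the noncoding RNA C02B4.8 and the small nucleolar RNA F26D10.24.

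Heat-shock chaperones fell in 12 of 18 and rose in 1, the same counts adjusted over the list alone, with a median of -0.41. For heat-shock chaperones, camera gave adjusted p = 2.78e-05, and adjusted p = 0.330 with an estimated correlation. The small heat-shock gene hsp-16.41 went from 39.3 ± 4.50 to 23.5 ± 4.08 FPKM (log2 change -0.77 ± 0.12, adjusted p = 0.000174) and the HSP40-type gene dnj-13 from 245 ± 11.02 to 192 ± 11.2 FPKM (log2 change -0.39 ± 0.066, adjusted p = 0.000336). The chaperone gene hsp-70, chosen after its values were seen, went from 50.8 ± 13.4 to 23.9 ± 6.61 FPKM (log2 change -1.11 ± 0.20, adjusted p = 0.000518). F44E5.4 and F44E5.5, HSP70-type genes that are near-identical copies, moved from 121 ± 37.3 to 49.2 ± 15.5 FPKM and from 121.6 ± 37.4 to 49.6 ± 15.6 FPKM. Reads shared between them leave each value uncertain, as they do within the hsp-16 family. Of 16 endoplasmic reticulum stress genes 3 fell and 1 rose, the same counts adjusted over the list alone (camera adjusted p = 0.201), among them hsp-4, from 184 ± 4.06 to 159 ± 6.105 FPKM (log2 change -0.23 ± 0.049, adjusted p = 0.00170). The score of these stress genes was -0.322 in TM replicate 5, -0.0848 to -0.0238 in the other TM libraries and -0.0406 to 0.0431 in the DMSO libraries.

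**Figure D3:**
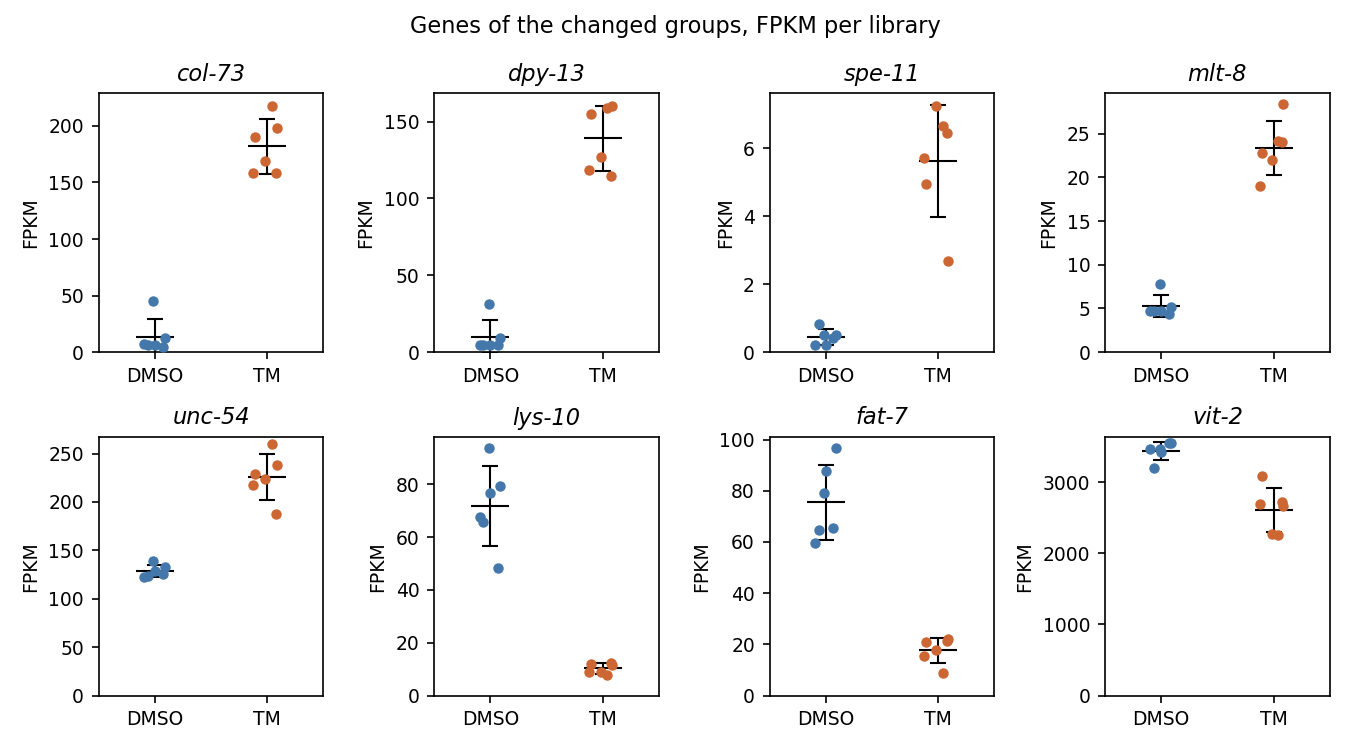
FPKM of 8 genes from the changed groups, 1 panel per gene, with a point per library, the horizontal mark at the group mean and bars of 1 SD (n = 6 per group). The TM values of col-73 lie between 158 and 218 FPKM, and the highest DMSO value, 45.5 FPKM, is that of replicate 6.

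Genes that handle copper moved in part, and neither of their lists passed. Of 16 copper transport and chaperone genes 5 rose and 2 fell (6 and 2 adjusted over the list alone), with a median change of 0.14 (camera adjusted p = 0.479). That median was 0.24 without DMSO replicate 6 and 0.086 without TM replicate 5. F58G6.9 (chromosome IV, 9651394 to 9652478, plus strand) rose (log2 change 1.04 ± 0.10, adjusted p = 3.73e-06), with 17.1 to 23.3 FPKM in the DMSO libraries and 34.4 to 48.6 FPKM in the TM libraries. The related gene F58G6.7 rose from 24.4 ± 2.22 to 30.6 ± 2.45 FPKM (log2 change 0.30 ± 0.073, adjusted p = 0.00529) and F31E8.4 fell from 34.4 ± 3.19 to 28.9 ± 2.005 FPKM (log2 change -0.28 ± 0.066, adjusted p = 0.00385). The copper chaperone gene cuc-1 (chromosome III, 7860466 to 7860985, minus strand) rose from 49.9 ± 4.53 to 65.9 ± 8.81 FPKM (log2 change 0.37 ± 0.10, adjusted p = 0.0103). The copper-exporting ATPase gene cua-1 (chromosome III, 13439730 to 13455307, minus strand) had 27.3 ± 3.53 FPKM in DMSO and 25.5 ± 4.02 FPKM in TM (log2 change -0.13 ± 0.10, adjusted p = 0.326), a difference within the spread between libraries. Copper-dependent enzymes outside mitochondria rose in 4 of 9 and fell in 1, the same counts adjusted over the list alone (camera adjusted p = 0.179). The tyrosinase genes tyr-4, from 13.3 ± 1.26 to 22.99 ± 2.52 FPKM (log2 change 0.76 ± 0.08, adjusted p = 7.12e-06), tyr-2 (log2 change 0.66 ± 0.09, adjusted p = 5.44e-05) and tyr-1 (log2 change 0.59 ± 0.093, adjusted p = 0.000199) rose. The octopamine synthesis gene tbh-1 fell (log2 change -0.32 ± 0.071, adjusted p = 0.00264). The copper-zinc superoxide dismutase gene sod-1 had 260.3 ± 11.4 FPKM in DMSO and 287 ± 38.7 FPKM in TM (log2 change 0.11 ± 0.091, adjusted p = 0.342), with TM replicate 5 the highest at 366 FPKM. The manganese form sod-3 had 5.09 ± 0.847 FPKM in DMSO and 5.00 ± 0.774 FPKM in TM (log2 change -0.061 ± 0.15, adjusted p = 0.762), and neither was past the threshold. Both passed with quantile normalization, sod-1 at 0.12 (adjusted p = 0.0353, in a range of alternatives up to 0.872) and sod-3 at -0.36 (adjusted p = 0.0196, in a range up to 0.997).

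Metallothionein and heavy-metal response genes rose in 6 of 8 and fell in 0, the same counts adjusted over the list alone, with a median of 0.73. For the metal response genes, camera gave adjusted p = 0.00293, and adjusted p = 0.189 with an estimated correlation. Without DMSO replicates 2 and 6 and TM replicate 5 the list no longer passed (adjusted p = 0.113, in a range of alternatives from 4.28e-05), with a median of 0.66. With quantile normalization 3 members rose. The cadmium-responsive genes cdr-4, from 31.5 ± 2.55 to 66.1 ± 5.31 FPKM (log2 change 1.04 ± 0.069, adjusted p = 5.89e-07), and cdr-2, from 24.5 ± 3.34 to 52.8 ± 6.95 FPKM (log2 change 1.08 ± 0.11, adjusted p = 6.75e-06), rose. The metallothionein gene mtl-2 was low in both groups, at 1.66 ± 0.677 FPKM in DMSO and 3.30 ± 0.844 FPKM in TM (log2 change 0.95 ± 0.27, adjusted p = 0.0130). Its call ended with quantile normalization (adjusted p = 0.173, in a range of alternatives from 0.00223). For mtl-1 the values were 3.02 ± 0.545 FPKM in DMSO and 3.21 ± 1.55 FPKM in TM (log2 change 0.057 ± 0.28, adjusted p = 0.884). Of 13 zinc and iron genes 4 rose and 4 fell, the same counts adjusted over the list alone, and the list did not pass, with a median of 0.15, a mean of 0.10 and a camera test that pointed down (adjusted p = 0.833). The ferritin gene ftn-1 (chromosome V, 7546468 to 7547579, minus strand) rose from 6.39 ± 1.85 to 17.5 ± 4.86 FPKM (log2 change 1.42 ± 0.23, adjusted p = 0.000254). The zinc transporter gene cdf-2 rose from 0.989 ± 0.317 to 2.56 ± 0.424 FPKM (log2 change 1.33 ± 0.21, adjusted p = 0.000157). The zinc transporter gene zipt-2.3 fell from 4.50 ± 0.709 to 1.802 ± 0.523 FPKM (log2 change -1.34 ± 0.19, adjusted p = 7.69e-05). The heme transporter gene hrg-4, chosen after its values were seen, fell from 3.69 ± 0.578 to 1.899 ± 0.266 FPKM (log2 change -0.98 ± 0.17, adjusted p = 0.000331).

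**Figure D4:**
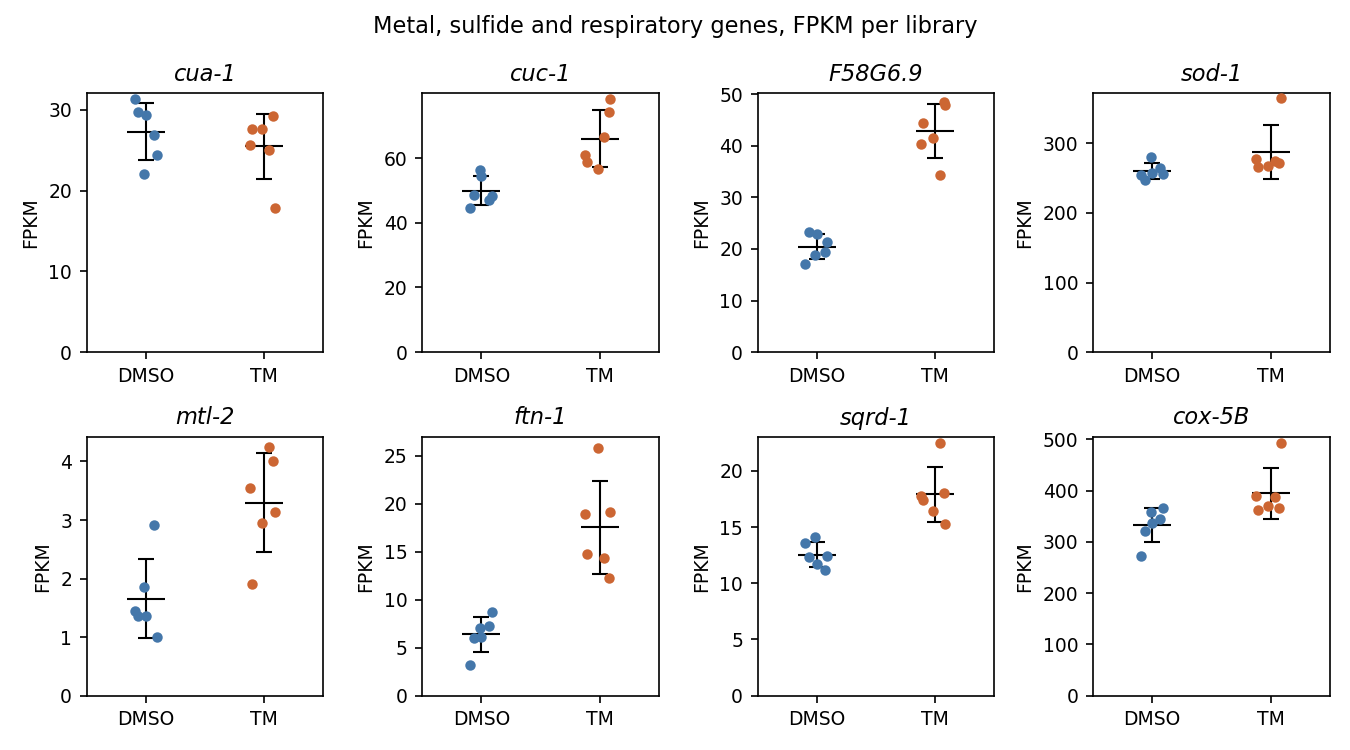
FPKM of 8 genes of metal handling, sulfide oxidation and respiration, 1 panel per gene, with a point per library, the horizontal mark at the group mean and bars of 1 SD (n = 6 per group). The groups do not overlap for cuc-1, F58G6.9, ftn-1 and sqrd-1, and overlap for cua-1, sod-1, mtl-2 and cox-5B.

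Some nuclear genes of the respiratory chain rose. Cytochrome c oxidase, a copper enzyme, had 3 of 15 subunit and assembly genes higher and 0 lower (2 and 0 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.507). The median was 0.11 without TM replicate 5. The heme synthesis gene cox-15 rose from 54.7 ± 3.85 to 70.9 ± 5.69 FPKM (log2 change 0.34 ± 0.082, adjusted p = 0.00413). The score of this list was 0.40 in TM replicate 5 against 0.049 to 0.16 in the other TM libraries, and DMSO replicate 6, at 0.30, lay above all of those. The subunit gene cox-5B, also known as cco-1, had 333 ± 33.9 FPKM in DMSO and 395 ± 49.7 FPKM in TM (log2 change 0.21 ± 0.10, adjusted p = 0.113). It passed in 8 of the alternatives, whose adjusted p ran from 0.00190 without DMSO replicates 2 and 6 and TM replicate 5 to 0.248. The copper delivery genes cox-17 (log2 change 0.12 ± 0.19, adjusted p = 0.646) and sco-1 (log2 change -0.051 ± 0.064, adjusted p = 0.543) did not pass. Complex I genes rose in 10 of 14 and fell in 0, the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0846). TM replicate 5 scored 0.476 for complex I against 0.173 to 0.247 in the other TM libraries. Complexes II and III and ATP synthase rose in 12 of 23 and fell in 0 (12 and 1 adjusted over the list alone), with a median of 0.27. Among them, 19 rose without DMSO replicates 2 and 6 and TM replicate 5. Their score was 0.635 in TM replicate 5 against 0.287 to 0.339 in the other TM libraries, and DMSO replicate 6 had the highest of the DMSO scores, 0.218. For these respiratory complexes, camera gave adjusted p = 0.00944, and adjusted p = 0.713 with an estimated correlation. Without DMSO replicate 5 or without TM replicate 3, 1 member fell. In that list ucr-2.2 went from 35.5 ± 2.302 to 50.7 ± 3.45 FPKM (log2 change 0.48 ± 0.074, adjusted p = 0.000141). The cytochrome c gene cyc-2.2 went from 0.511 ± 0.347 to 5.26 ± 1.27 FPKM (log2 change 3.28 ± 0.35, adjusted p = 8.13e-06). Mitochondrial stress genes rose in 6 of 12 and fell in 0, the same counts adjusted over the list alone (camera adjusted p = 0.313). Their score in TM replicate 5, -0.0105, lay apart from the 0.182 to 0.237 of the other TM libraries. The mitochondrial HSP70-type gene hsp-6 went from 256 ± 13.5 to 335 ± 27.9 FPKM (log2 change 0.36 ± 0.079, adjusted p = 0.00251).

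Hydrogen sulfide and HIF-1 response genes rose in 5 of 12 and fell in 0, the same counts adjusted over the list alone, without the list passing (camera adjusted p = 0.0846). The sulfide oxidation gene sqrd-1 went from 12.56 ± 1.09 to 17.9 ± 2.45 FPKM (log2 change 0.48 ± 0.094, adjusted p = 0.00108) and cysl-1 from 17.3 ± 1.47 to 28.5 ± 2.58 FPKM (log2 change 0.69 ± 0.089, adjusted p = 3.70e-05). The gene phy-2, a prolyl hydroxylase that acts on collagen, went from 7.98 ± 0.386 to 17.6 ± 3.94 FPKM (log2 change 1.11 ± 0.12, adjusted p = 1.19e-05). Levels of cysl-2 were 39.9 ± 5.16 FPKM in DMSO and 38.3 ± 5.39 FPKM in TM (log2 change -0.087 ± 0.11, adjusted p = 0.566). Of 27 genes of sulfur amino acids and the molybdenum cofactor 9 rose and 6 fell (11 and 6 adjusted over the list alone, camera adjusted p = 0.376). The S-adenosylmethionine synthetase gene sams-5 went from 1.77 ± 0.339 to 8.42 ± 1.02 FPKM (log2 change 2.21 ± 0.15, adjusted p = 5.89e-07). The cystathionine lyase gene cth-1 went from 3.79 ± 0.481 to 9.76 ± 1.88 FPKM (log2 change 1.33 ± 0.14, adjusted p = 5.74e-06). The cysteine dioxygenase gene cdo-1 had 25.3 ± 3.82 FPKM in DMSO and 22.1 ± 3.55 FPKM in TM (log2 change -0.22 ± 0.11, adjusted p = 0.122). It passed without TM replicate 1 (log2 change -0.29, adjusted p = 0.0462, in a range of alternatives up to 0.339). Antioxidant and SKN-1 phase II genes rose in 6 of 21 and fell in 0, the same counts adjusted over the list alone (camera adjusted p = 0.436). The glutathione S-transferase gene gst-4 went from 19.7 ± 3.11 to 32 ± 5.29 FPKM (log2 change 0.67 ± 0.13, adjusted p = 0.000943).

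Detoxification families rose in part. UDP-glucuronosyltransferases rose in 24 of 49 and fell in 1 (27 and 1 adjusted over the list alone), with a median of 0.44. With quantile normalization 15 rose and 8 fell. The gene ugt-62 went from 73.2 ± 9.53 to 146 ± 28.5 FPKM (log2 change 0.97 ± 0.11, adjusted p = 1.66e-05). For the UDP-glucuronosyltransferases, camera gave adjusted p = 0.000610, and adjusted p = 0.619 with an estimated correlation. Cytochrome P450 genes rose in 19 of 41 and fell in 2 (20 and 2 adjusted over the list alone), with a median of 0.35. Quantile normalization turned that median to -0.027, with 12 genes higher and 9 lower, and the list no longer passed (adjusted p = 0.154, in a range of alternatives from 4e-05). For the P450 genes, camera gave adjusted p = 0.00384, and adjusted p = 0.607 with an estimated correlation. Without DMSO replicate 6 the call was lost as well (adjusted p = 0.0947), while the median stayed at 0.38. The number of P450 genes that fell was 5 without TM replicate 5, 0 without TM replicate 1 and 1 without DMSO replicate 1 or without TM replicate 3, 4 or 6. Among them cyp-14A1 went from 1.95 ± 0.312 to 6.33 ± 1.47 FPKM (log2 change 1.67 ± 0.17, adjusted p = 5.44e-06) and cyp-35A3 from 3.10 ± 0.763 to 8.20 ± 1.39 FPKM (log2 change 1.38 ± 0.15, adjusted p = 1.09e-05). In TM replicate 5 the scores of both families lay near the DMSO mean, at -0.049 and 0.02, against 0.54 to 0.63 and 0.49 to 0.63 in the other TM libraries. Glutathione S-transferases rose in 15 of 35 and fell in 0. ABC exporters rose in 7 of 22 and fell in 3, and both had the same counts adjusted over the list alone (camera adjusted p = 0.0846 and 0.658). TM replicate 5 scored 0.523 for the transferases and -0.229 for the exporters, against 0.177 to 0.358 and 0.227 to 0.281 in the other TM libraries.

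Epidermal antimicrobial peptide genes rose in 6 of 9 and fell in 0, the same counts adjusted over the list alone, with a median of 1.12. For the antimicrobial peptides, camera gave adjusted p = 0.00727, and adjusted p = 0.452 with an estimated correlation. The neuropeptide-like antimicrobial gene nlp-33 went from 8.35 ± 3.04 to 25.4 ± 5.75 FPKM (log2 change 1.57 ± 0.22, adjusted p = 7.41e-05), and nlp-29 from 3.09 ± 1.02 to 6.84 ± 1.103 FPKM (log2 change 1.12 ± 0.20, adjusted p = 0.000569). The list no longer passed without DMSO replicate 6 (adjusted p = 0.0550, median 1.16) or without DMSO replicates 2 and 6 and TM replicate 5 (adjusted p = 0.187, median 1.03), in a range of alternatives from 0.00281. Its median stayed about as large in both. Intracellular pathogen response genes rose in 5 of 13 and fell in 0. C-type lectins rose in 12 of 71 and fell in 16. Both had the same counts adjusted over the list alone and neither list was past the threshold (camera adjusted p = 0.332 and 0.179). The lectin gene clec-70 fell from 9.40 ± 1.08 to 4.25 ± 0.783 FPKM (log2 change -1.17 ± 0.12, adjusted p = 7.30e-06), whereas clec-4 rose from 20.6 ± 1.17 to 33.1 ± 3.47 FPKM (log2 change 0.66 ± 0.083, adjusted p = 3.06e-05).

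Cytosolic ribosomal protein genes rose in 39 of 79 and fell in 0 (47 and 0 adjusted over the list alone), with a median of 0.29. The gene rpl-11.2 rose from 285 ± 30.1 to 515 ± 55.5 FPKM (log2 change 0.82 ± 0.10, adjusted p = 2.46e-05). For the ribosomal proteins, camera gave adjusted p = 0.000125, and adjusted p = 0.735 with an estimated correlation. The number that rose was 19 without DMSO replicate 1, 20 without DMSO replicate 4, 20 without DMSO replicate 5 and 62 without DMSO replicate 6. The score of TM replicate 5, 0.64, lay above the 0.16 to 0.31 of the other TM libraries, and DMSO replicate 6, at 0.28, lay within that range. After length correction the median of the ribosomal protein genes was 0.20. Proteasome genes fell in 3 of 33 and rose in 0, the same counts adjusted over the list alone, with a median of -0.14. In that list 7 fell without DMSO replicate 5, 23 without TM replicate 5 and 18 with quantile normalization. The proteasome score of TM replicate 5 was 0.0595 against -0.251 to -0.129 in the other TM libraries. For the proteasome genes, camera gave adjusted p = 0.00242, and adjusted p = 0.713 with an estimated correlation. The regulatory subunit gene rpn-12 went from 187 ± 6.33 to 162 ± 5.57 FPKM (log2 change -0.24 ± 0.054, adjusted p = 0.00291). Of 36 genes of glycolysis, the TCA cycle and the glyoxylate cycle 11 rose and 3 fell. Of 46 genes of lipolysis and fatty acid oxidation 8 rose and 5 fell, and of 11 DAF-16 targets 2 rose and 3 fell. All 3 had the same counts adjusted over the list alone (camera adjusted p = 0.347, 0.754 and 0.374). The glycolytic gene aldo-1 rose from 110.5 ± 8.53 to 193 ± 26.6 FPKM (log2 change 0.77 ± 0.10, adjusted p = 3.55e-05). The glyoxylate cycle gene icl-1 rose from 214 ± 12.8 to 299 ± 29.1 FPKM (log2 change 0.45 ± 0.083, adjusted p = 0.000697). Autophagy and lysosome genes rose in 5 of 49 and fell in 5 (2 and 4 adjusted over the list alone). Histones rose in 13 of 55 and fell in 14 (13 and 15 adjusted over the list alone), with camera adjusted p of 0.234 and 0.330. TM replicate 5 scored 0.288 for glycolysis and the cycles, -0.123 for autophagy and 0.514 for histones. The other TM libraries had 0.0588 to 0.114, -0.0233 to -0.00567 and -0.103 to 0.0223. Histones had a median of -0.040 and a mean of 0.058, and the sign of both depended on single libraries. With 1 library left out the histone median ran from -0.16 without TM replicate 5 to 0.014 without DMSO replicate 3. Their mean was -0.057 without TM replicate 5 and 0.0025 without DMSO replicate 1. The median was negative and the mean positive for lipolysis and fatty acid oxidation (-0.058 and 0.15) and C-type lectins (-0.071 and 0.070), with the camera test pointing down. The lipolysis median was -0.027 without TM replicate 5. For C-type lectins, without DMSO replicate 6 the median was -0.026 and the mean 0.11, and the mean was 0.046 without TM replicate 5 or without DMSO replicate 4. For DAF-16 targets the median was 0.022, the mean -0.092 and the test direction down. Leaving out 1 library moved the DAF-16 median from -0.10 (TM replicate 1) to 0.076 (DMSO replicate 6) and the mean from -0.14 (TM replicate 5) to -0.032 (DMSO replicate 6).

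Of the 41 lists tested, 17 passed with the preset correlation, 12 upward and 5 downward. With a correlation estimated from the data camera called 0 of them, the lowest adjusted p being 0.162. In that test 6 lists had an unadjusted p under 0.05. The fry test, which asks whether a list changed at all and not whether it changed more than other genes, called 29.

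**Figure D5:**
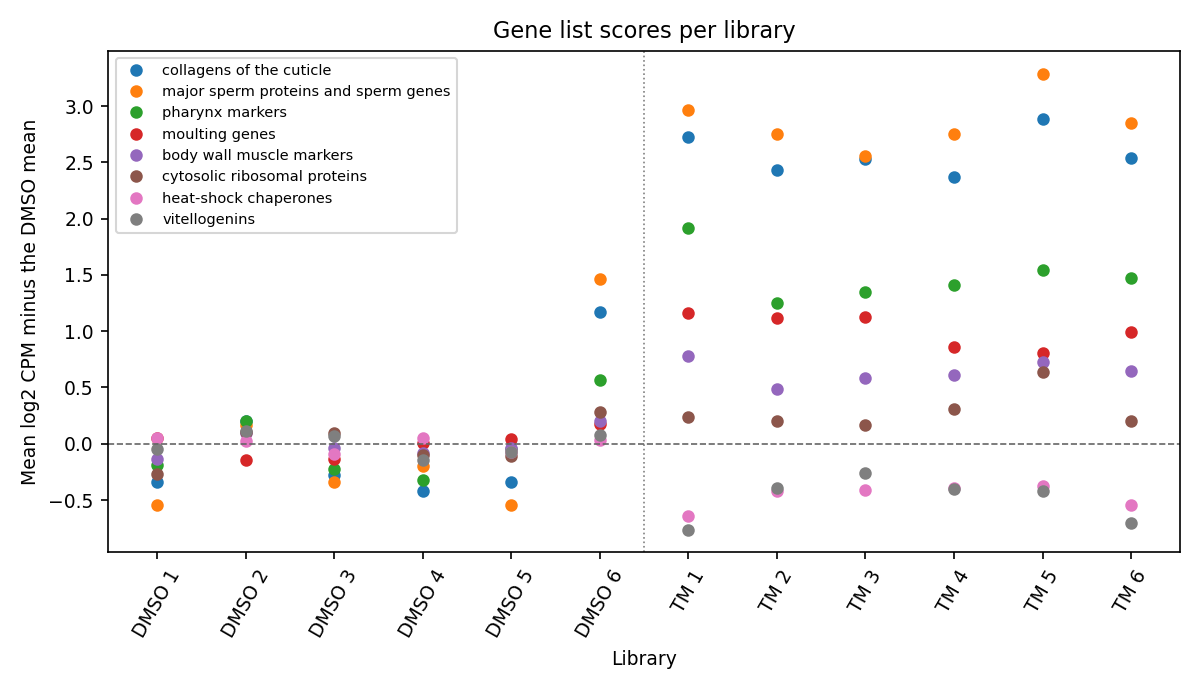
Mean log2 CPM of the members of 8 gene lists in each of the 12 libraries, minus the mean of the 6 DMSO libraries, with 1 point per list and library. DMSO replicate 6 lies at 1.17 for the collagens and 1.46 for the sperm genes, between the other DMSO libraries and the TM libraries.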

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

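The tests of TM material in DMSO replicate 6 were chosen after that library had been seen, and the tests for transcript length were written before their results. A Dixon test was run on log2(FPKM + 1) for each named gene and group. It asked whether the lowest or highest of 6 values lies far from its neighbour for the width of the group. It marked 50 of 396 groups, 12.63%, where about 5% is expected by chance, and 34 of the marked values lay in DMSO replicate 6 (14) or TM replicate 5 (20).

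DMSO replicate 6 had the highest DMSO value for the collagens dpy-13 (31.6 FPKM, the others 4.58 to 9.04), dpy-4 (35.2), dpy-5 (40.8), col-138 (38.2), col-90 (2.79), col-92 (81.8) and dpy-7 (4.72). The same held for the sperm genes smz-1 (2.44) and gsp-4 (3.25), the moulting gene mlt-8 (7.84), the myosin gene myo-3 (10.1), the heme gene cox-10 (8.73) and the glycolytic gene aldo-1 (127.5). Its cyp-34A9 value of 3.83 FPKM was the lowest of the group.

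TM replicate 5 had the highest TM value for cox-6A (302.5 FPKM), cox-5A (813), cox-5B (494), nduf-11 (224), timm-23 (182), rpl-11.2 (626), sod-1 (366) and cyb-1 (338). It had the lowest for tbh-1 (108), spg-7 (25.99), fasn-1 (15.8), vha-5 (13.9), atg-18 (116), rpn-3 (149), qua-1 (1.85) and cyp-14A1 (3.39). The same held for haf-9 (9.89), unc-64 (9.97), hsp-70 (12.05) and the copper ATPase gene cua-1 (17.8, the others 25.03 to 29.18).

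In TM replicate 1, acdh-6 (4.11 FPKM), nlp-33 (36.8), cnc-4 (13.6), myo-3 (19.8) and flp-9 (36.7) were high and haf-4 (12.08) was low. TM replicate 3 was high for cdr-7 (6.80) and ucr-2.2 (57.5), and TM replicate 6 for F26D10.24 (0.890) and rpn-5 (161). DMSO replicate 3 was low for qua-1 (0.591), gst-22 (8.85) and unc-25 (2.57), and DMSO replicate 4 for vit-2 (3197). In DMSO replicate 5 lys-3 (0.294) was low and ifa-1 (7.099) high.

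The place of DMSO replicate 6 between the groups might come from TM material in that library. The share that would account for it had a median of 21.4% (95% bootstrap interval 19.7 to 23.8) over 81 collagens, 26.2% (23.1 to 28.3) over 49 sperm genes and 21.9% (20.4 to 23.2) over 478 other genes that rose at least 4-fold, of which 43 had a share under 5% and 13, argk-1 among them, lay below the level it would bring. These intervals are over genes of 1 library that can move together, so they do not measure the spread between libraries. Against TM material, DMSO replicate 6 had the highest DMSO value of lys-10 (93.5 FPKM), which fell in TM. It also had the lowest DMSO scores of P450 genes (-0.14) and UDP-glucuronosyltransferases (-0.26), which rose. Over 27 genes that fell at least 2-fold the median share was -12.57% (-32.8 to 25.7), or -0.495% (-9.15 to 30.5) after length correction, intervals too wide to decide, and TM material and animals at an earlier stage both stay open. Transcript length is argued against as the whole cause, since the collagen excess over the other DMSO libraries was 1.58 before length correction and 1.5 after it (SD of the others 0.21).

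TM replicate 5 might stand apart because of transcript length, since its slope on log2 length was -0.19 with the other TM libraries between 0.0090 and 0.085. Its distance from the other TM libraries on the second component went from 51.4 to 42.9 after length correction (SD of the others 3.09), which argues against length as the whole cause. Other causes were not tested.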

How the results depend on the processing

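The settings without DMSO replicates 2 and 6 and TM replicate 5, with length correction, with total counts only and with DESeq2 were chosen after the data had been seen. So was the comparison with limma on log2(FPKM + 1), the test first planned. In every setting except quantile normalization all genes called there and in the edgeR model had the same direction, and with it 3112 of 3114 did. The 4590 changed genes became 2649 (1630 higher, 1019 lower) at a mean of at least 5 FPKM, where 26 lists passed. With a limit of 1 on the log2 scale they became 1079 (1051 higher, 28 lower). Genes lower in TM, 1851, became 2945 with quantile normalization and 2832 without the 3 libraries that stand apart. DESeq2 called 5177 and limma on log2(FPKM + 1) 4597. With 1 library left out, 3974 to 5343 genes passed, 2457 to 2949 higher and 1517 to 2394 lower, and 15 to 19 lists. In place of 17 lists, 0 passed with an estimated correlation in camera. With fry, which tests against no change and so answers another question, 29 passed. The proteasome list, called by camera, did not pass with fry (adjusted p = 0.0664). Of 100 random splits of the 12 libraries, drawn from 462, only the real one, 1 of 100, reached 4590 genes. The highest other split gave 1218. A split that mixes TM and DMSO libraries widens the spread within its groups, which lowers its gene count. The labels name no cultures, so a chance difference between cultures is not excluded by these splits. As many lists passed in 37 of 100 splits, with up to 25 in another split. Many splits put unequal numbers of TM libraries on their 2 sides and so keep part of the treatment difference. The split with 25 lists had 1 TM library on 1 side. Splits with 3 TM libraries on each side share the treatment evenly. Most of those gave fewer than 17 lists, but 1 gave 19 and another 18. As many lists can thus pass at the preset correlation with the treatment shared evenly, and chance is not excluded for their number. Named genes kept their direction and call in 5222 of 5298 values. They lost their call in 24 (10 of them with quantile normalization), gained one in 32 and reversed in 20. Of the genes reversed only numr-2 had passed. Most named genes were picked through the edgeR model, where 186 of 198 passed, so much of this agreement was fixed by the choice. Of all 4590 calls, 67.8% also passed with quantile normalization. The change of numr-2 turned to -0.029 with quantile normalization. For sod-3, -0.061, it turned to 0.00080 at 5 FPKM, 0.038 with array weights, 0.076 without the 3 libraries and between -0.13 and 0.027 with 1 library left out. For mtl-1, 0.057, it was -0.034 with the replicate block, -0.0082 with a pseudocount of 0.1, -0.38 with quantile normalization, -0.11 with array weights, -0.097 with length correction, -0.013 without the 3 libraries and between -0.21 and 0.18 with 1 library left out. For cox-17 it was -0.20 with quantile normalization and -0.028 with length correction, and for sco-1 0.010 at 5 FPKM, 0.00048 with array weights and 0.0052 without the 3 libraries. The cause was not tested. The replicate block gave 3633 genes (2328 higher, 1305 lower) and 18 lists. Same-numbered libraries had correlations of their deviations from -0.38 to 0.26, 2 of 6 over 0.1, and 2 numbers had their own number as the best match, so the numbers were not read as pairs.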

Other observations

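Gene ontology terms, and the genes below that no list holds, were chosen after the results had been seen, as was the test of developmental timing. Cell cycle genes fell more often than other annotated tested genes, 74 of 166 against 26.8 expected (hypergeometric adjusted p = 2.53e-15). Germline terms fell with them, such as meiotic cell cycle in 36 of 103 (16.7 expected) and P granule in 24 of 65 (10.5 expected). DNA replication genes fell in 28 of 64 (10.4 expected, adjusted p = 1.77e-05) and origin-binding genes in 11 of 14 (2.26 expected, adjusted p = 3.87e-05). The replication helicase gene mcm-7 went from 256 ± 16.51 to 210.0 ± 9.53 FPKM (log2 change -0.32 ± 0.07, adjusted p = 0.00240), and mcm-3 (log2 change -0.30 ± 0.053, adjusted p = 0.000453), the mitotic kinase gene cdk-1 (log2 change -0.29 ± 0.067, adjusted p = 0.00329) and the cyclin gene cyb-1 (log2 change -0.37 ± 0.078, adjusted p = 0.00188) fell as well. Among annotated genes, 8904 over 895 terms, 73 terms passed for falls and 65 for rises. The hypergeometric test takes genes as independent of each other, and genes that move together can make its p too small. No term was tested with a correlation between genes, and camera with an estimated correlation called 0 of the 41 lists.

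Terms that rose included pseudopodium, the crawling arm of nematode sperm, with 17 of 20 genes (4.44 expected, adjusted p = 6.15e-07). The term spermatogenesis went the other way, with 18 of 49 genes lower (7.92 expected, hypergeometric adjusted p = 0.00908). Of those 18 genes, 16 were in none of the lists. Intermediate filament genes rose in 12 of 14 (3.11 expected, adjusted p = 5.52e-05), with ifa-1 going from 5.64 ± 0.751 to 10.9 ± 1.43 FPKM (log2 change 0.93 ± 0.10, adjusted p = 6.20e-06) and ifp-1 from 0.801 ± 0.228 to 2.99 ± 0.923 FPKM (log2 change 1.87 ± 0.22, adjusted p = 1.68e-05). Protein tyrosine phosphatases rose in 25 of 47 (10.4 expected, adjusted p = 0.000196), and the sperm phosphatase genes gsp-3 (log2 change 3.17 ± 0.34, adjusted p = 9.62e-06) and gsp-4 (log2 change 3.16 ± 0.43, adjusted p = 5.65e-05) rose too, gsp-4 by 3.85 without DMSO replicate 6. Genes of the defense response to Gram-negative bacteria rose in 28 of 77 (17.1 expected, adjusted p = 0.0449), and those against Gram-positive bacteria fell in 20 of 51 (8.25 expected, adjusted p = 0.00261). Metalloendopeptidases rose in 25 of 50 (11.1 expected, adjusted p = 0.000728). The arginine kinase gene argk-1, which regenerates ATP, went from 0.144 ± 0.0657 to 5.16 ± 1.86 FPKM (log2 change 5.08 ± 0.30, adjusted p = 5.89e-07).

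The joint rise of collagens and sperm genes, with falls of yolk and oocyte genes, might mean that TM animals were at an earlier point of development, since larvae make cuticle and sperm before oocytes and yolk. The adult-stage collagen col-19 also rose, which runs the other way, from 358 to 490 FPKM in the DMSO libraries to 714 to 929 in the TM libraries. The moulting regulator nhr-23 overlapped, at 25.4 to 27.6 FPKM in DMSO and 24.1 to 26.8 in TM. The median change of the vitellogenins, -0.53, only restates the fall of yolk genes and tests nothing. The treatment and any delay fall in the same 6 libraries and no stage is given, so this stays open. Transcript length is argued against as the cause, because the lower of the corrected medians of collagens and sperm genes stayed at 2.90. The doubtful libraries do not carry it either, since 99.4% of the risen collagens and sperm genes still passed without DMSO replicates 2 and 6 and TM replicate 5. Males among the TM animals could raise sperm genes, and 5 measured male neuron genes had a median change of 0.15, but all lay below 1 FPKM, so they exclude nothing.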
